A study of Homo sapiens with 6 samples.

How the data were processed

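RNA sequencing of bone marrow CD34+ cells was compared between 3 patients grouped as high beta-catenin and 3 grouped as low beta-catenin, with 1 library per patient. Per the labels' protocols, RNA was extracted with a Qiagen AllPrep kit, and total RNA libraries were made with a stranded Illumina TruSeq kit whose last PCR step used KAPA HiFi enzyme. Total RNA libraries are not selected for poly(A) tails, so transcripts without a tail, such as replication-dependent histone messenger RNAs, can be captured. How beta-catenin was measured to form the groups, in which cells, and with what limit was not given in the sources used here.

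Estimated counts per gene symbol, as deposited by the authors, were the main measurement. They were made with kallisto on hg38/GRCh38, per the submitters' processing notes, and the kallisto version, the transcript annotation and the rule for summing transcripts to genes were not given in the sources used here. kallisto assigns reads to transcripts by sequence and divides reads that match several transcripts, so genes with near-identical copies (ribosomal protein genes, histones, NBPF1, HNRNPA1 and NPM1 among the genes named) carry uncertain values. Whether the counting used the strand of the reads was likewise not given, so reads of overlapping genes on opposite strands could not be told apart here. The deposited estimated counts were already whole numbers and entered the tests without further rounding. A second table held TPM, transcript abundance corrected for length, as deposited by the authors. Its 6 columns summed to between 634201 and 910035 per library, so the tables list part of what was quantified. Ribosomal RNA and most small RNA genes other than pseudogenes were not analysed here.

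The table listed 30160 genes, and 361 Y-linked genes and XIST were removed before any test. Library totals were 28712644, 27912163 and 27689538 estimated counts in the low group and 32586193, 18814842 and 32227744 in the high group. Genes with too few counts were removed with edgeR's filterByExpr, which left 15379 genes holding 99.9% of the counts. Library sizes were scaled by the trimmed mean of M values (TMM). Levels are given as TMM-scaled CPM, counts relative to the size of the scaled library, and log2 CPM used a prior count of 2. The high and low groups were compared with edgeR's robust quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are log2 of high over low throughout. Each standard error (SE) is the size implied by the fold change and its p-value in the edgeR test, and is not an independent measure of spread. Single values were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Shares of single libraries have 95% Clopper-Pearson intervals, which cover counting error only.

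Before the data were examined, 32 gene lists were fixed: Wnt and Notch pathways and targets, blood lineage and stem cell markers, stromal, endothelial and immune cell markers, cell cycle, stress and signalling responses, and housekeeping complexes. Of their members, FAM30A and the symbol CYR61 were not listed in the table, which lists the latter gene as CCN1. Lists were tested with camera in edgeR at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. camera asks whether a list moved relative to all other genes. The same test with the correlation estimated for each list, and fry, were run as alternatives. For fry the directional test is given unless its mixed test is named. Members were also counted with p-values adjusted over the list alone.

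The rule for genes named in the text was also fixed before the data were examined. CTNNB1, CD34, AXIN2, LEF1, TCF7, MYC, CCND1, HES1, HEY1, NOTCH1 and JAG1 were always named. Because fewer than 5 genes per direction passed, the 5 genes per direction with the smallest p were named, among those with mean log2 CPM of at least 1 and no overlap between groups, and they are stated not to pass. From each called list, up to 4 members with the smallest p in the direction of the list were eligible. PLCG2, RIMBP3B, ZNF277, RIMBP3 and members of the mitochondrial genome were chosen after their values were seen. Coordinates are those of GENCODE release 29 on GRCh38, counted from 1.

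The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings and filters, edgeR without robust moderation, other thresholds, the patient number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), and each library left out in turn. Alternatives added after seeing the data removed genes that share sequence with 7SK RNA, removed a trend with transcript length (a loess curve of span 0.3 per library on relative effective length, taken from the ratio of counts to TPM), or left out low library 1 and high library 3 together. 7SK sequence was sought as shared stretches of 31 bases between RN7SK (328 bases) and the GENCODE transcripts. The stretches were counted with overlaps, so several can lie in 1 longer run and their number is not a number of separate segments.

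The test was checked on simulated counts for the 15379 genes, with the means and library sizes of these 6 libraries. At the spread fitted to these data, edgeR recovered 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 16 of 50 changed 8-fold and 32 of 50 changed 16-fold at adjusted p under 0.05, with 1 false call. With the dispersion set to 0.05, it recovered 23, 49, 50 and 50 of 50, with 8 false calls. In simulated counts with independent genes, camera called the 1 shifted list and 0 of the others. This check does not cover correlated genes, and the estimated correlation was 0.80 for ribosomal protein and 0.86 for S phase genes.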

Results

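Transcripts were counted in CD34+ cells, the blood stem and progenitor fraction carrying the CD34 surface protein, from the bone marrow of 6 patients. The series concerns myeloid malignancies and the bone marrow niche, and its design set 3 patients with high beta-catenin against 3 with low beta-catenin. Beta-catenin, encoded by CTNNB1, carries Wnt signals to the nucleus and also joins cadherins at cell contacts. Library totals ran from 18814842 to 32586193 estimated counts. More genes had at least 1 count in the high libraries, 17869 ± 258 against 16386 ± 901 (SD, n = 3 each, exact permutation p = 0.1, the smallest the design allows). Libraries of the same group were only slightly more alike than libraries of different groups: correlations of log2 CPM were 0.83 to 0.86 within the high group, 0.79 to 0.86 within the low group and 0.78 to 0.84 between groups. The patients are different people in each group, so the spread between libraries includes all differences between patients.

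The comparison asked which transcripts distinguished CD34+ cells of high beta-catenin patients from those of low beta-catenin patients. Whether the libraries held the same mix of cells was not tested. CD34 transcripts ranged from 11.5 CPM in high library 3 to 769 CPM in low library 1, so a different mix is not excluded. In the high libraries, the HOXA and HOXB transcription factor genes and their partner PBX3 were higher, by a median of 3.25 on the log2 scale over 14 genes. Ribosomal protein transcripts (median −1.93), replication-dependent histone transcripts (median −2.23) and immediate early genes such as EGR1 and FOSB (median −2.02) were lower. On the log2(TPM + 1) scale the medians of these lists were 3.72 for HOX genes, −1.17 for ribosomal protein, −1.61 for histone and −0.995 for immediate early genes. All 4 lists were called by edgeR's camera at a preset correlation. Each had adjusted p = 0.365 with an estimated correlation, however, and none was called by fry's directional test (adjusted p from 0.253 to 0.296). Transcripts of CTNNB1 itself were not higher in the high group, and target genes of Wnt signalling showed no common direction. Patients within a group differed widely, and no single gene passed the test over all genes in edgeR.

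CTNNB1 (GRCh38 chromosome 3, 41194741 to 41260096, plus strand, protein-coding) had 202 ± 27.5 CPM in the high libraries and 297 ± 73.5 CPM in the low libraries (SD, n = 3 each). The high libraries stood at 173, 206 and 227 CPM, all below the low libraries at 251, 258 and 382 CPM (exact permutation p = 0.1, the smallest possible). The edgeR log2 fold change was −0.56 (SE 0.29), with adjusted p = 0.581. Without low library 3 it was −0.33, and scaled by library totals alone it was −0.16. On the log2(TPM + 1) scale the difference was −0.018, and the groups overlapped, with 70.5, 90.8 and 147 TPM in the low libraries and 85.4, 98.1 and 109 TPM in the high libraries. The scalings placed the typical gene differently. The median log2 fold change of all tested genes was 0.088 with TMM, 0.071 with DESeq2 size factors, 0.50 with library totals alone and 0.54 on the log2(TPM + 1) scale. Relative to that median gene, CTNNB1 lay at −0.64, −0.64, −0.66 and −0.55 in the same order.

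**Figure D1:**
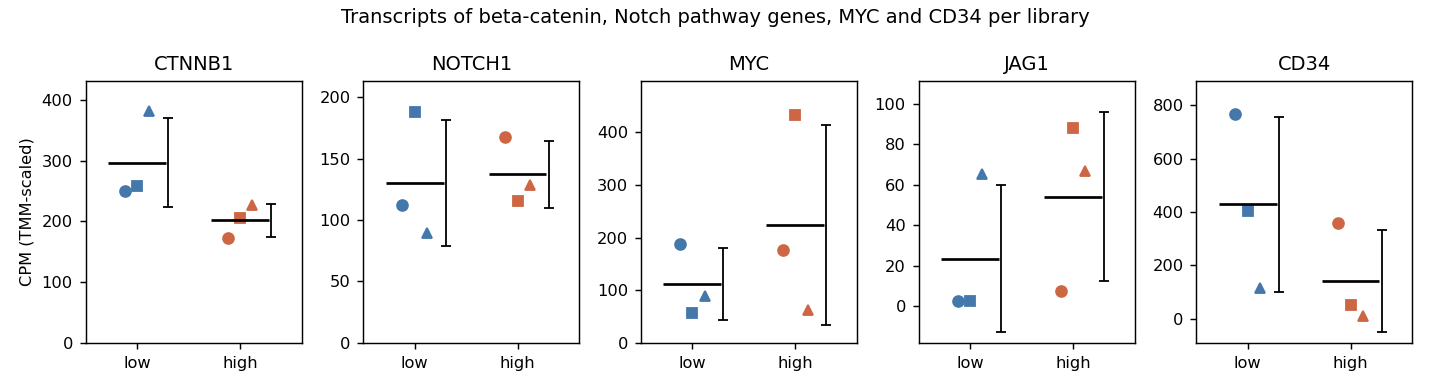
TMM-scaled CPM (vertical axes) of CTNNB1, NOTCH1, MYC, JAG1 and CD34 in the 3 low (blue) and 3 high (orange) libraries; circles, squares and triangles are patients 1, 2 and 3, the horizontal line is the group mean and the bar beside it the mean ± SD. The CTNNB1 points do not overlap on this scale (high 173 to 227, low 251 to 382), though they do on the TPM scale, while those of NOTCH1, MYC, JAG1 and CD34 overlap.

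Among direct readouts of Wnt signalling, AXIN2 was close to absent. This feedback inhibitor of the pathway had 18 counts in high library 3 and 0 in the other 5 libraries. LEF1, a partner of beta-catenin on DNA, had 224 counts in high library 2, 35 in low library 3, 2 in high library 1 and 0 elsewhere. CCND1, which encodes cyclin D1, had 2049 counts in low library 2 and at most 9 in each other library. These 3 genes were too low in most libraries to be tested. TCF7, another DNA-binding partner of beta-catenin, had a log2 fold change of −0.30 (SE 1.19), whose sign changed with the scaling (0.0065 with library totals, 0.27 on the log2(TPM + 1) scale). MYC stood at 224 ± 189 CPM in the high and 111 ± 68.2 CPM in the low libraries (SD, n = 3 each; log2 fold change 1.00, SE 0.74). It was highest in high library 2 (432 CPM), and without that library the log2 fold change was 0.10. The Wnt target list had 7 of 18 tested genes higher and 11 lower, with a median of −0.21, a mean of 0.015 and a camera test pointing down (edgeR's camera, adjusted p = 0.319). Its median was above 0 with library totals (0.06) and on the TPM scale (0.05), where the median gene stood at 0.50 and 0.54. Relative to the median gene the list lay at −0.29 with TMM, −0.44 with library totals and −0.48 on the TPM scale. With 1 library left out and genes filtered anew, the median of the Wnt target list ran from −1.05 without high library 3 to 0.14 without low library 3. Wnt pathway components were split, 15 higher and 16 lower of 31 (median −0.049, edgeR's camera, adjusted p = 0.566). Their median was 0.34 with library totals and 0.49 on the TPM scale. Relative to the median gene it was −0.14 with TMM, −0.15 with library totals and −0.05 on the TPM scale.

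Notch pathway genes, which pass signals between neighbouring cells, also showed no called shift. NOTCH1 had 137 ± 27.1 CPM in the high and 130 ± 51.6 CPM in the low libraries (SD, n = 3 each; log2 fold change 0.076, SE 0.35). JAG1, which encodes a Notch ligand, ranged from 2.64 to 87.7 CPM over the 6 libraries (log2 fold change 1.2, SE 1.41, and 4.35 without low library 3). HES1, a Notch target, had 14, 9 and 4 counts in the low libraries and 0 in each high library, a difference of a few reads that the filter kept out of the test. HEY1 had 0 counts in every library. Notch pathway components were higher in 14 of 23 tested genes (median 0.26) and Notch targets in 6 of 12 (median 0.029, mean −0.12, test pointing up), with adjusted p of 0.566 and 0.599 in edgeR's camera.

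Over all 15379 genes tested, edgeR called 0 genes at adjusted p under 0.05, the smallest adjusted p being 0.247. At an unadjusted p under 0.05 there were 1547 genes, 693 higher and 854 lower in the high libraries, where chance gives about 769. The groups did not overlap for 2784 genes, 18.1% of those tested, where chance gives 10%. limma-voom and limma on TPM values also called 0 genes, with 1644 and 3074 genes at an unadjusted p under 0.05. DESeq2 had 2180 genes at an unadjusted p under 0.05 and called 569, 207 higher and 362 lower. Of the 569 called by DESeq2, 531 were in the edgeR test, all with an unadjusted edgeR p under 0.05. The direction of the unadjusted calls depends on the scaling: 44.8% were higher in the high libraries with TMM and 81.4% (1672 higher, 383 lower) with library totals alone. On the log2(TPM + 1) scale the split was 2778 higher and 296 lower.

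The 10 genes named for the smallest p, none of which passed in edgeR, were 5 per direction. OSBPL5, a lipid transfer protein gene (chromosome 11, 3087116 to 3166739, minus strand), had 103 ± 26.4 CPM in the high and 16.8 ± 1.97 CPM in the low libraries (SD, n = 3 each), a log2 fold change of 2.61 (SE 0.31). PBX3, a HOX cofactor gene (chromosome 9, 125747345 to 125967377, plus strand), had 175 ± 23.6 and 37.6 ± 8.53 CPM in that order, a log2 fold change of 2.22 (SE 0.29). CARD9, an adaptor of innate immune receptors, had a log2 fold change of 2.83 (SE 0.42), and NBPF1, whose near-identical copies make its counts uncertain, of 1.83 (SE 0.31). C3AR1, a complement receptor gene, had 1, 5 and 1 counts in the low libraries and 249, 1774 and 1072 in the high libraries, so that its fitted log2 fold change of 8.61 (SE 1.22) rests on very few counts in the low group. The lower genes were led by PPP1R15A, a stress-induced regulator of translation (chromosome 19, 48872392 to 48876057, plus strand), with 142 ± 31.04 CPM in the high and 858 ± 155 CPM in the low libraries (SD, n = 3 each; log2 fold change −2.59, SE 0.33). CSRNP1 (−3.83, SE 0.50), the cAMP phosphodiesterase gene PDE4B (−3.96, SE 0.57) and the histone genes H3C4 (−3.00, SE 0.43) and H4C1 (−2.76, SE 0.39) followed. All 10 had adjusted p = 0.247 in edgeR, and all 10 passed in DESeq2.

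camera called 16 of the 32 lists in edgeR at the preset correlation of 0.01, 1 higher and 15 lower in the high libraries. With the correlation estimated for each list it called 0, the smallest adjusted p being 0.365, and fry's directional test also called 0. In fry's mixed test, which ignores direction, the HOX, ribosomal protein, histone and immediate early lists each had adjusted p = 0.0491. Lists that camera did not call also passed it, such as heat shock genes (0.00852), while G2 and M phase genes, which camera called, did not (0.340). Calls of 6 lists held whichever single library was left out: HOX genes, ribosomal proteins, histones, immediate early genes, oxidative phosphorylation, and G2 and M phase. Every called list kept its direction relative to the median gene under all 4 scalings. So did Wnt target, Wnt component, stromal cell and glycolysis genes, which were not called and whose own medians changed sign. No member of any list passed over all genes tested in edgeR, as given above, and the counts that follow are adjusted over the list alone.

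**Figure D2:**
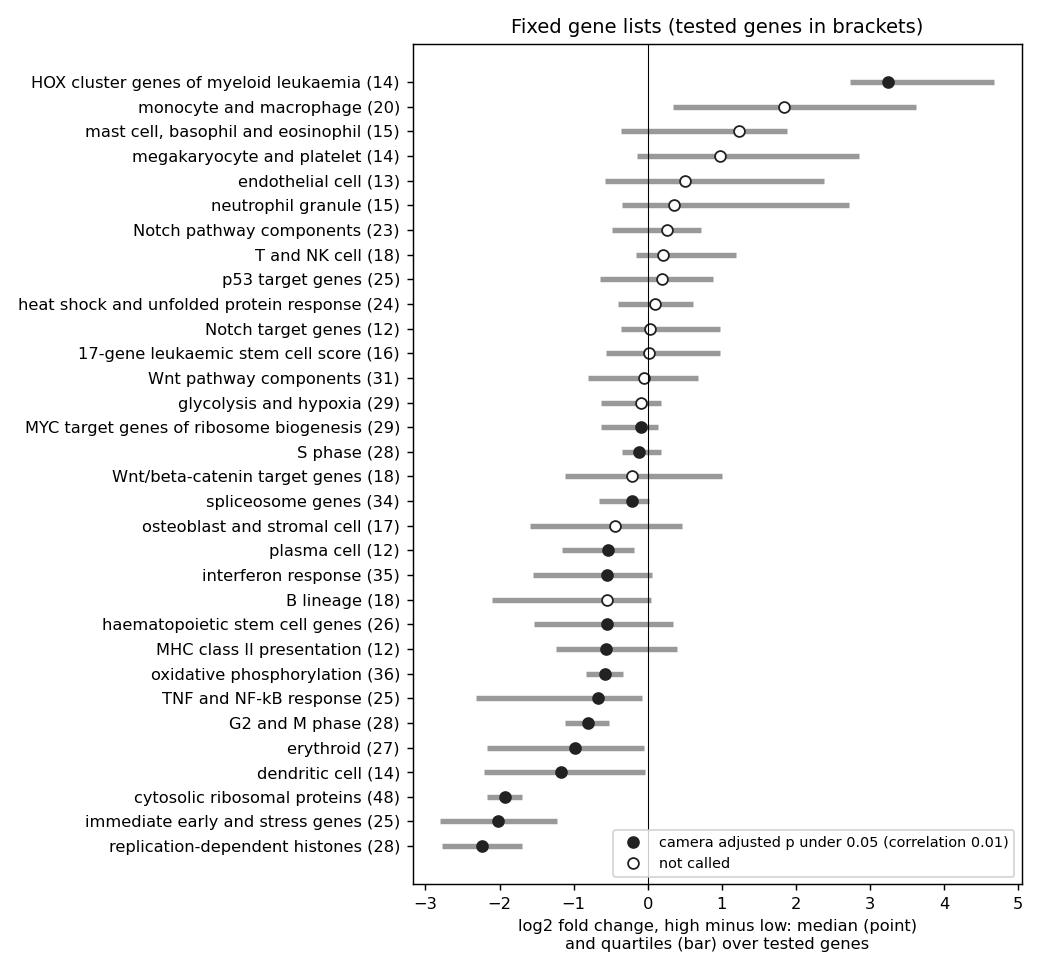
Median (point) and quartiles (bar) of the log2 fold change, high minus low, over the tested genes of each of the 32 fixed lists, with the number of tested genes in brackets; filled points are lists called by camera at the preset correlation. The HOX list stands at 3.25, and the histone, immediate early and ribosomal protein lists at −2.23, −2.02 and −1.93.

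The HOX list holds genes that pattern the body axis and mark immature and leukaemic myeloid cells. All 14 tested members were higher in the high libraries, with a median of 3.25 and quartiles of 2.73 and 4.67. In 11 of the 14 the groups did not overlap, against 18.1% of all tested genes. The members varied together (estimated correlation 0.50), so these 11 are not independent outcomes. Adjusted over the list alone, PBX3 and HOXB4 rose, 2 of the 14. Within the HOXB cluster, HOXB4 (chromosome 17, 48575513 to 48580111, minus strand) had 46.8 ± 36.1 CPM in the high and 1.40 ± 1.42 CPM in the low libraries (SD, n = 3 each; log2 fold change 5.06, SE 1.15). HOXB3 had 157 ± 142 and 4.03 ± 6.13 CPM (log2 fold change 5.28, SE 1.85), and HOXB6 60.4 ± 79.7 and 0.550 ± 0.757 CPM (log2 fold change 6.75, SE 2.13), in that order. On the annotation HOXB4 lies within HOXB3 and HOXB6 overlaps it, all on the minus strand, so the division of reads among these genes is uncertain, and HOXB6 had only 17 counts in high library 1. The list passed edgeR's camera with adjusted p = 1.52e-12 at the preset correlation, and had adjusted p = 0.365 with an estimated correlation. Its level was lowest in low library 1, and without that library the median of the 14 genes was 2.68. It was 3.86 without low library 2, 3.30 without low library 3 and 3.45 without high library 1. Without high library 2 the log2 fold change of HOXB3 was 4.44 and that of HOXB6 4.77.

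The ribosomal protein list covers proteins of the cytosolic ribosome. All 48 tested members were lower in the high libraries, with a median of −1.93 (quartiles −2.16 and −1.70), the groups did not overlap for any of the 48, and all 48 fell when adjusted over the list alone. RPS27 had 320 ± 22.9 CPM in the high and 2342 ± 1163 CPM in the low libraries (SD, n = 3 each; log2 fold change −2.87, SE 0.47), and RPL10A had 328 ± 50.5 and 1432 ± 465 CPM (log2 fold change −2.13, SE 0.36). RPS13 (−2.12, SE 0.36) and RPS15 (−2.09, SE 0.36) differed by similar amounts. The 48 genes together took 2.77 ± 0.465% of the counts in the high and 7.69 ± 1.81% in the low libraries (SD, n = 3 each, exact permutation p = 0.1). The list passed edgeR's camera with adjusted p = 2.97e-70 at the preset correlation, and had adjusted p = 0.365 with an estimated correlation. These proteins have many processed pseudogenes, which took 0.231 ± 0.0421% of the counts in the high and 0.655 ± 0.194% in the low libraries (SD, n = 3 each). Other measured differences ran the same way: the shortest decile of transcripts had a median of −0.29, against −0.033 to 0.17 in the other deciles, and mitochondrially encoded messenger RNAs took 0.876 ± 0.32% of counts in the high and 1.68 ± 0.135% in the low libraries (SD, n = 3 each, exact permutation p = 0.1).

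Replication-dependent histone genes, which are short, lack introns and are copied in near-identical sets, were lower for all 28 tested members (median −2.23, quartiles −2.78 and −1.70), of which 20 did not overlap between groups and 21 fell when adjusted over the list alone. H2AC8 had 126 ± 47.1 CPM in the high and 978 ± 537 CPM in the low libraries (SD, n = 3 each; log2 fold change −2.95, SE 0.52), and H2AC13 (−2.93, SE 0.47) and H4C8 (−2.64, SE 0.44) were close to it. The list took 0.468 ± 0.254% of counts in the high and 1.13 ± 0.301% in the low libraries (SD, n = 3 each, exact permutation p = 0.1). It passed edgeR's camera with adjusted p = 2.25e-35 at the preset correlation, and had adjusted p = 0.365 with an estimated correlation. Oxidative phosphorylation genes of the nuclear genome were lower in 33 of 36 (median −0.58), led by COX4I1 (−1.37, SE 0.36), UQCRB (−1.72, SE 0.45) and NDUFA4 (−1.61, SE 0.48), although the median was 0.09 on the TPM scale, where the median gene stood at 0.54. That list passed edgeR's camera with adjusted p = 1.28e-06 at the preset correlation, and had adjusted p = 0.615 with an estimated correlation.

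**Figure D3:**
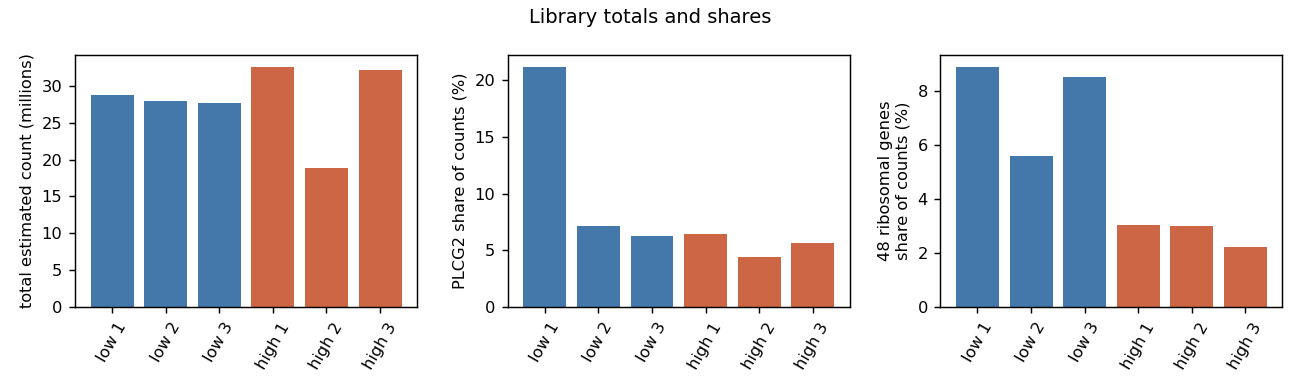
Total estimated counts, the share of counts assigned to PLCG2 in percent and the share assigned to the 48 ribosomal protein genes in percent (vertical axes), 1 bar per library, low in blue and high in orange. Totals range from 18814842 to 32586193, PLCG2 from 4.38% to 21.2%, and the ribosomal share is 2.23% to 3.05% in the high and 5.61% to 8.92% in the low libraries.

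One gene, PLCG2, which encodes a phospholipase of immune receptor signalling (chromosome 16, 81739097 to 81962693, plus strand), took 21.2% of the counts of low library 1 (95% Clopper-Pearson interval 21.19 to 21.22) and 4.38% to 7.20% of the other 5. The share was 5.49 ± 1.04% in the high and 11.5 ± 8.38% in the low libraries (SD, n = 3 each, exact permutation p = 0.2). Its transcripts contain sequence of 7SK, an abundant small nuclear RNA, and its counts are therefore uncertain. Without the genes that share 7SK sequence, edgeR again called 0 genes (1546 at an unadjusted p under 0.05) and camera 16 lists.

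Immediate early and stress genes, which respond within minutes to growth factors, stress or handling, were lower in 20 of 25 (median −2.02). The mean level of the list was highest in low library 3 (2.01), and low library 1 (−0.13) stood at about the level of high library 3 (−0.12). The median was −1.30 without low library 3 and −2.65 without high library 3. EGR1 had 12.6 ± 6.41 CPM in the high and 349 ± 286 CPM in the low libraries (SD, n = 3 each; log2 fold change −4.80, SE 0.81), FOSB 63.5 ± 39.3 and 777 ± 461 CPM (−3.61, SE 0.70), and IER2 35.8 ± 9.0 and 126 ± 13.3 CPM (−1.82, SE 0.30), in that order. Adjusted over the list alone, 12 members fell and 1 rose, the heat shock gene HSPH1 (log2 fold change 1.79, SE 0.53), which was named after its value was seen. The list passed edgeR's camera with adjusted p = 1.52e-12 at the preset correlation, and had adjusted p = 0.365 with an estimated correlation. Genes of the TNF and NF-kB response were lower in 20 of 25 (median −0.67), with NFKBIA, the inhibitor of NF-kB (−2.77, SE 0.46), the chemokine gene CXCL8 (−5.04, SE 1.35), CD83 (−3.21, SE 0.89) and NFKBIZ (−2.32, SE 0.68) leading. Without low library 3 the log2 fold change of CXCL8 was −2.93 and that of CD83 −2.07, and without high library 3 the median of the list was −1.58. NFKBIA was the 1 member that fell when adjusted over the list alone. Interferon response genes were lower in 26 of 35 (median −0.54, but 0.10 on the TPM scale), among them EPSTI1 (−2.26, SE 0.46), IFI44L (−3.26, SE 0.93) and MX1 (−1.88, SE 0.78). Without low library 3 IFI44L was at −1.83 and MX1 at −0.63. Of these genes, 0 of 35 passed adjusted over the list alone in edgeR, with 4 at an unadjusted p under 0.05. In edgeR's camera the TNF list had adjusted p = 0.000164 and the interferon list adjusted p = 0.00423, and each had adjusted p = 0.615 with an estimated correlation. Without low library 3 neither was called (adjusted p = 0.0813 and 0.0778 in edgeR's camera).

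**Figure D4:**
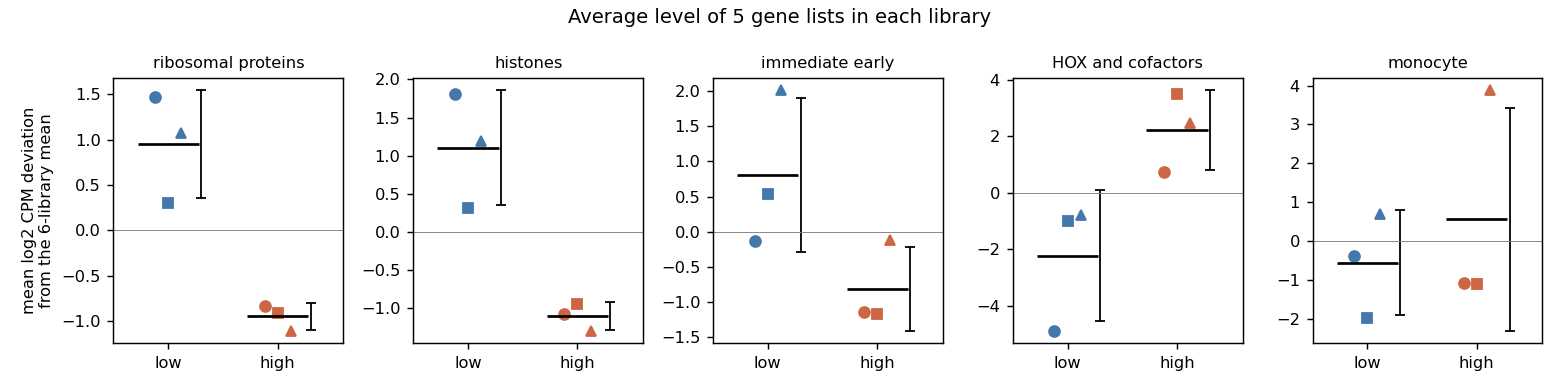
Mean deviation of log2 CPM from the 6-library mean (vertical axes) over the genes of 5 lists, in the 3 low (blue) and 3 high (orange) libraries; circles, squares and triangles are patients 1, 2 and 3, with the group mean as a line and the mean ± SD beside it. Ribosomal protein and histone levels of the high libraries lie between −1.30 and −0.83, below all low libraries; low library 1 is lowest for HOX genes (−4.90) and high library 3 is highest for monocyte genes (3.88).

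Among markers of blood lineages, CD34 itself had 141 ± 191 CPM in the high and 428 ± 329 CPM in the low libraries (SD, n = 3 each; log2 fold change −1.61, SE 1.23), and ranged from 11.5 CPM in high library 3 to 769 CPM in low library 1. Its log2 fold change was −0.86 without low library 1 and −3.79 without high library 1. Haematopoietic stem cell genes were lower in 16 of 26 (median −0.56), with NRIP1 (−1.73, SE 0.46), ROBO4 (−3.03, SE 0.84), NPR3 (−4.88, SE 1.68) and PROM1 (−3.71, SE 1.56) leading. Their call (edgeR's camera, adjusted p = 0.0294 at the preset correlation; adjusted p = 0.615 with an estimated correlation) ended without low library 1, low library 2 or high library 3 (adjusted p = 0.0582, 0.279 and 0.229 in edgeR's camera). NPR3 was at −7.44 without high library 2 and PROM1 at −5.64 without high library 1. The 17-gene leukaemic stem cell score, of which 16 genes were tested, was split 8 to 8 (median 0.015, whose sign changed with the scaling and the libraries left out; edgeR's camera, adjusted p = 0.673). Erythroid genes were lower in 21 of 27 (median −0.99), led by HEMGN (−4.52, SE 1.38) and AHSP, which stabilises alpha-globin (−4.58, SE 2.12). HEMGN was highest in low library 1 (357 CPM) and AHSP in low library 3 (82.7 CPM), and without those libraries their log2 fold changes were −2.32 and −1.23. The mean level of the list was highest in low library 3 and high library 2. Its median was 0.10 without low library 3, −1.57 without low library 1 and −3.73 without high library 2. Their adjusted p in edgeR's camera was 0.00966 at the preset correlation (adjusted p = 0.739 with an estimated correlation) and 0.485, 0.132 and 0.111 without low library 3, high library 1 or high library 3. Dendritic cell genes were lower in 10 of 14 (median −1.17), among them IRF8 at 58.9 ± 88.0 CPM in the high and 326 ± 55.9 CPM in the low libraries (SD, n = 3 each; log2 fold change −2.47, SE 1.28). IRF8 stood at 13.2, 3.08 and 160 CPM in high libraries 1, 2 and 3. Without high library 3 its log2 fold change was −5.31. Plasma cell genes were lower in 10 of 12 (median −0.54), among them SSR4 (−1.25, SE 0.43) and JCHAIN (−4.07, SE 1.44). The dendritic list had adjusted p = 0.0468 in edgeR's camera (adjusted p = 0.615 with an estimated correlation) and lost its call without low library 2, high library 1 or high library 2 (0.455, 0.123 and 0.0815), with a median of −0.38 without low library 2. The plasma cell list had adjusted p = 0.0152 in edgeR's camera (adjusted p = 0.518 with an estimated correlation) and lost it without low library 3 or high library 3 (0.151 and 0.0885) and on log2(TPM + 1) (0.0517). MHC class II genes were lower in 8 of 12 (median −0.57), with CD74 at 1780 ± 1926 CPM in the high and 3929 ± 1302 CPM in the low libraries (SD, n = 3 each; log2 fold change −1.14, SE 0.94). Their adjusted p in edgeR's camera was 0.0435 (adjusted p = 0.723 with an estimated correlation) and 0.196, 0.0627 and 0.586 without low library 1, low library 3 or high library 2. Without high library 3 the median was −1.44. On the log2(TPM + 1) scale the medians were −0.15 for haematopoietic stem cell, −0.28 for erythroid, −0.16 for dendritic cell, −0.012 for plasma cell and −0.10 for MHC class II genes.

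Monocyte and macrophage genes were higher in 19 of 20 (median 1.84), yet the list was not called (edgeR's camera, adjusted p = 0.0515). Its mean level was 3.88 in high library 3, 0.70 in low library 3 and below 0 in the other 4 libraries. Without high library 3 the median was −1.92 and the test pointed down (adjusted p = 0.0633 in edgeR's camera), and it was called as higher without low library 3, high library 1 or high library 2 (adjusted p = 0.00927, 0.000282 and 0.000141). It was also called as higher with the patient number as a replicate block, with DESeq2 size factors and without a filter on low counts (adjusted p = 0.00885, 0.0484 and 0.00655 in edgeR's camera). Other lists of cell types were not called in edgeR's camera: megakaryocyte and platelet genes (median 0.98, adjusted p = 0.311), neutrophil granule genes (0.35, 0.344), T and NK cell genes (0.21, 0.319), mast cell, basophil and eosinophil genes (1.23, 0.566), B lineage genes (−0.54, 0.121), osteoblast and stromal cell genes (−0.44, 0.319, with a median of 0.02 on the TPM scale) and endothelial cell genes (0.50, 0.530). Of these, neutrophil granule genes without low library 3 (adjusted p = 0.00041), B lineage genes without low library 3 or high library 1 (0.00041 and 0.0244), mast cell genes without high library 3 (0.0181) and stromal cell genes without low library 1 (0.0209) were called. With the replicate block, megakaryocyte genes were called as higher and B lineage genes as lower (adjusted p = 0.0418 and 0.0231 in edgeR's camera). Megakaryocyte genes were also called without a filter on low counts (0.0329), B lineage genes with a strict filter (0.0435) and on log2(TPM + 1) (0.00116), and stromal cell genes on log2(TPM + 1) (0.0138). With genes filtered anew, the neutrophil granule median ran from −0.18 without low library 2 to 4.48 without low library 3. The mast cell median was −0.35 without high library 2 and at least 0.93 without any other single library.

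All 28 tested G2 and M phase genes were lower in the high libraries (median −0.80), 6 of them without overlap between groups, with CCNA2 at 14.3 ± 7.66 CPM in the high and 44.6 ± 22.98 CPM in the low libraries (SD, n = 3 each; log2 fold change −1.64, SE 0.59), CDC20 at −1.54 (SE 0.61) and CENPA at −2.29 (SE 1.00). The mean level of the list was lowest in high library 2 (−2.15), and high library 1 (0.46) lay within the range of the low libraries (0.054 to 1.22). Without high library 1 the median was −1.42. Its adjusted p in edgeR's camera was 6.86e-07 at the preset correlation and adjusted p = 0.615 with an estimated correlation, and 0.02 without high library 2. S phase genes, among them E2F1 (−1.34, SE 0.56), MCM4 (−0.80, SE 0.44) and MCM2 (−0.73, SE 0.51), had a median of only −0.12, which was 0.26 with library totals and 0.25 on the TPM scale. Their call (edgeR's camera, adjusted p = 0.0446; adjusted p = 0.741 with an estimated correlation) ended without low library 3, high library 2 or high library 3 (adjusted p = 0.33, 0.841 and 0.499), and also on log2(TPM + 1) (0.0986) and with a strict filter on low counts (0.0554). The S phase median was −1.01 without high library 1, and above 0 without high library 2 (0.18) or high library 3 (0.13).

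MYC targets of ribosome biogenesis were lower in 17 of 29 (median −0.096), with NPM1, a nucleolar chaperone gene, at 608 ± 116 CPM in the high and 1713 ± 553 CPM in the low libraries (SD, n = 3 each; log2 fold change −1.49, SE 0.36), ODC1 at −1.51 (SE 0.50) and FBL at −1.07 (SE 0.39). Spliceosome genes were lower in 24 of 34 (median −0.22), among them SNRPD2 (−1.55, SE 0.40), SRSF3 (−0.76, SE 0.25) and HNRNPA1 (−0.99, SE 0.35). Both medians lay above 0 with library totals (0.34 and 0.18) and on the TPM scale (0.26 and 0.32). In edgeR's camera the MYC target list had adjusted p = 0.0162 (adjusted p = 0.741 with an estimated correlation), 0.218 without low library 3 and 0.273 without high library 3, and the spliceosome list adjusted p = 0.00691 (adjusted p = 0.615 with an estimated correlation), 0.0627 and 0.0583 without the same libraries. On log2(TPM + 1) neither was called (adjusted p = 0.153 and 0.387 in camera). Glycolysis and hypoxia genes (median −0.085, but 0.31 with library totals; adjusted p = 0.167), p53 targets (median 0.19, mean 0.012, test pointing down; adjusted p = 0.356) and heat shock and unfolded protein response genes (median 0.099, mean 0.044, test pointing down; adjusted p = 0.778) were not called in edgeR's camera. Glycolysis genes were called as lower without low library 2 or high library 3 (adjusted p = 0.0139 and 0.0129), and p53 targets without high library 3 (0.0243). Within these lists PPP1R15A fell, as did 2 p53 targets, PMAIP1 (log2 fold change −2.45, SE 0.43) and CCNG1 (−2.21, SE 0.52), when adjusted over the list alone, and both of the latter were named after their values were seen.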

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

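The settings without 7SK-sharing genes, with the length trend removed and with low library 1 and high library 3 both left out, and the alternatives of the count at unadjusted p, were chosen after the data were seen, and the other settings before. edgeR called 0 genes under every setting run, limma-voom and limma on TPM called 0, and DESeq2 called 569. At an unadjusted p under 0.05 edgeR had 1547 genes and DESeq2 2180. DESeq2 also tested genes that the edgeR filter had removed. The cause of the gap between edgeR and DESeq2 was not tested. Of the 569, 513 had no overlap between groups, and in 11 of the 569 over 90% of the CPM came from 1 library. Genes picked for a group difference tend to separate in the same libraries, so the lack of overlap does not weigh the calls. The unadjusted count was 3074 for limma on log2(TPM + 1), 3062 for log2(TPM + 0.1) and 3306 without a filter on low values, and ran from 1227 to 1803 over the 6 fits that left out 1 library. With the patient number as a replicate block the unadjusted count was 1418, edgeR again called 0 genes and camera 19 lists. The numbers do not pair the patients: deviations of same-numbered libraries correlated at 0.016, 0.079 and −0.019.

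camera called 0 lists with an estimated correlation and fry's directional test called 0, while the 14 other settings called 11 to 19. Leaving out 1 library gave 11 to 16 called lists, with 11 without low library 3, where 8 of the 16 calls remained. With low library 1 and high library 3 both left out there were 14 called lists, 12 of them among the 16. CTNNB1 kept its direction under all settings run, from −0.68 to −0.33 over the fits without 1 library and −0.018, −0.017 and −0.018 in the 3 fits to TPM. Of the 81 genes with a fit that the naming rule or a later choice selected, 74 never changed sign. Most of them were picked by p and direction in these same libraries, so a kept sign was largely fixed by the choice. Of the genes always named, TCF7 and NOTCH1 turned. TCF7 turned to 0.34 in limma-voom, 0.0065 with library totals, 0.24 with the replicate block and 0.27, 0.92 and 0.27 in the 3 TPM fits (pseudocount 1, pseudocount 0.1, no filter), and ran from −0.95 to 1.27 with 1 library left out. In the same 3 TPM fits CD38 turned to 0.30, 0.31 and 0.30, MCM5 to 0.13, 0.13 and 0.13 (0.058 with library totals), HLA-DPB1 to 0.058, 0.084 and 0.058 and RFX5 to 0.25, 0.25 and 0.25. NOTCH1 was −0.0011 with the length trend removed and ran from −0.13 to 0.42 with 1 library left out, and SPTB ran from −3.35 to 0.58.

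Beyond the fits without 1 library, the estimated correlation and fry, 7 of the 16 calls ended in some setting. Their adjusted p in camera was 0.0517 for plasma cell, 0.153 for MYC target, 0.387 for spliceosome and 0.0986 for S phase genes on log2(TPM + 1), 0.0554 for S phase and for MHC class II genes with the strict filter, and 0.0534 for dendritic cell genes without a filter. It was 0.0964 for haematopoietic stem cell and 0.116 for dendritic cell genes with the length trend removed, although their medians were then −0.69 and −1.28, no nearer 0 than before (−0.56 and −1.17). With low library 1 and high library 3 both left out it was 0.25 for haematopoietic stem cell, 0.306 for S phase, 0.283 for MYC target and 0.0695 for spliceosome genes. Calls were gained by megakaryocyte genes without a filter (0.0329) and with the replicate block (0.0418), and by monocyte genes with DESeq2 size factors (0.0484), without a filter (0.00655) and with the replicate block (0.00885). B lineage genes gained one with the strict filter (0.0435), with the replicate block (0.0231) and on log2(TPM + 1) (0.00116). With low library 1 and high library 3 both left out stromal cell and glycolysis genes gained one (0.00442 and 0.00834), and stromal cell genes also on log2(TPM + 1) (0.0138).

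Lists whose camera direction turned were called in neither direction in those fits. Their adjusted p on log2(TPM + 1) was 0.81 for the leukaemic stem cell score, 0.988 for megakaryocyte, 0.913 for neutrophil granule, 0.533 for mast cell, 0.728 for endothelial and 0.533 for heat shock genes. With the filter on low counts changed it was 0.648 for Notch targets (no filter) and 0.966 for T and NK cell genes (strict filter). With the replicate block it was 0.838 for the leukaemic stem cell score, and for heat shock genes it was 0.866 with the length trend removed and 0.935 in fry. With low library 1 and high library 3 both left out it was 0.846 for Notch targets, 0.306 for Notch components and 0.122 for monocyte genes. With 1 library left out the adjusted p ran from 0.253 to 0.963 for Wnt components, 0.213 to 0.998 for Notch targets, 0.246 to 0.888 for Notch components, 0.0599 to 0.841 for the leukaemic stem cell score, 0.000141 to 0.458 for monocyte, 0.0181 to 0.689 for mast cell, 0.251 to 0.759 for endothelial, 0.263 to 0.585 for heat shock and 0.0129 to 0.80 for glycolysis genes. The cause of these turns was not tested. At the spread of these libraries, edgeR recovered 0 of 50 simulated genes changed 2-fold, 0 of 50 changed 4-fold, 16 of 50 changed 8-fold and 32 of 50 changed 16-fold, so single genes with differences of 4-fold or less were likely to be missed.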

Other observations

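The gene families below, and all tests of this part except the splits counted on called lists and on the ribosomal protein and HOX medians, were chosen after the results were seen. Messenger RNAs of the mitochondrial genome, which encode subunits of the respiratory chain, were lower in the high libraries for all 13 genes (median log2 fold change −1.26, and −0.63 on the TPM scale), 9 of them without overlap between groups. MT-CO3 had a log2 fold change of −1.85 (SE 0.45) and MT-ND1 of −1.60 (SE 0.39), while MT-ATP8 stood at −0.32 (SE 0.60). The family passed edgeR's camera with adjusted p = 7.69e-11 over 8 families, and had adjusted p = 0.2 with an estimated correlation. Translation initiation and elongation factors were lower in 47 of 64 (median −0.46, but 0.13 on the TPM scale; edgeR's camera, adjusted p = 5.84e-07, and adjusted p = 0.2 with an estimated correlation). Mitochondrial ribosomal proteins (median −0.41, 62 of 79 lower) and proteasome subunits (median −0.23, 33 of 48 lower) were also called in edgeR's camera (adjusted p = 0.000303 and 0.00359, each with adjusted p = 0.726 with an estimated correlation), and both medians lay above 0 on the TPM scale (0.33 and 0.39). Zinc finger genes of the ZNF series (median 0.20, 311 of 485 higher), solute carriers (median 0.19), lysine methyltransferases and demethylases (median 0.24) and chaperonin subunits (median −0.28, but 0.44 on the TPM scale) were not called (adjusted p = 0.207, 0.287, 0.741 and 0.287 in edgeR's camera). The median gene stood at 0.54 on the TPM scale. Relative to it, translation factors lay at −0.40, mitochondrial ribosomal proteins at −0.20, proteasome subunits at −0.15 and chaperonin subunits at −0.095.

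The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share of splits under 0.05. With 0 genes called by edgeR at adjusted p under 0.05 in the real split (569 in DESeq2), that count cannot be compared between splits. The 1547 genes at an unadjusted p under 0.05 compare with at most 742 in another split, so that 1 of 10 splits gave as many. camera called 16 lists in the real split and 19 in the highest other, so 2 of 10 gave as many. That highest split set low library 1, low library 3 and high library 3 against the rest. Each of the other splits called from 7 to 19 lists, so the number of calls does not set high against low apart. The absolute median of the ribosomal protein list was 1.93 against at most 1.31 elsewhere, and that of the HOX list 3.25 against at most 2.01, each 1 of 10.

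PLCG2 took 4.38% to 21.2% of the counts per library, a share without parallel among the other genes named here. A candidate explanation is that reads of 7SK RNA, a nuclear RNA without a poly(A) tail that total RNA libraries retain, were assigned to PLCG2. Its transcripts share 89 stretches of 31 bases, counted with overlaps, with RN7SK, which the table does not list. RIMBP3B, on another chromosome, shares 4 such stretches and 258 with the related copy RN7SKP63, and its log2 ratio to PLCG2 had an SD of only 0.0853 over the 6 libraries (38.4 to 44.8 RIMBP3B counts per 1000 PLCG2 counts), at percentile 0.0065 of all tested genes, where 7SK reads predict a fixed ratio. More PLCG2 messenger RNA alone predicts a slope near 0 of RIMBP3B on PLCG2, and the slope was 1.01. ZNF277 (5 stretches) had an SD of 0.293, with 4 genes below it, whereas RIMBP3, which shares as many stretches as RIMBP3B (4 and 258), ran opposite to PLCG2 (slope −3.38). 7SK reads alone do not explain that, and whether 7SK itself differs between the patients stays open.

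Ribosomal protein and histone transcripts were lower in the high libraries (medians −1.93 and −2.23), and both sets are short. Removing the trend with transcript length left medians of −1.54 (quartiles −1.72 and −1.28) and −1.67 (quartiles −1.93 and −0.89). Lists of other genes matched on length and abundance had 2.5th percentiles of −1.04 and −1.09. These lists were redrawn from 112 genes for each set, so the percentiles describe a small pool and not independent lists. Within that limit, the values argue against length as the whole cause. The matched genes were less abundant than the ribosomal list by 0.89 on the log2 scale, however, and length may account for part of it. Loss of reads to pseudogenes predicts a gain there, but the pseudogene share changed by −0.423 percentage points while the list lost 4.92. Fewer cells in S phase, as a cause of the histone difference, predict S phase genes lower by a comparable amount. Their median was −0.12, but −1.01 without high library 1, and G2 and M phase genes were lower (median −0.80), so this explanation stays open. A difference between the patients' cells, in RNA quality or in the capture of RNA, all of which the groups carry with them, stays open too and was not tested.

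HOX genes were higher in the high libraries (median 3.25). Their mean level was lowest in low library 1 (−4.90), against −1.01 and −0.78 in low libraries 2 and 3. Without low library 1 the median was 2.68 (quartiles 2.14 and 4.34), and with the length trend removed it was 3.16, which argues against that library or transcript length as the whole cause. HOX levels differ between genetic types of myeloid leukaemia and between stages of blood cell maturation, and either may underlie the difference with or without a link to beta-catenin. The design gives 1 library per patient and no other grouping, so these were not tested.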
